A study of Caenorhabditis elegans with 2 samples.

How the data were processed

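The assay was ChIP-seq of a GFP-FLAG-tagged CEH-82 protein in whole fourth-stage larvae of Caenorhabditis elegans strain OP212, which carries the unc-119(ed3) mutation and the transgene ddEx58, per the labels. The transgene's name marks an extrachromosomal array while the labels also speak of an insertion, and which of these it is was not settled. The labels give 2 biological replicates of 1 group and fragmentation by sonication. The control that the authors called peaks against, per the deposited lists of files, was not analysed here. No processing from reads was done here.

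The deposited lists were peak lists in narrowPeak form on the builds ce10 and ce11. Each replicate had a list described in the deposited text as peaks and background prepared for an irreproducible discovery rate (IDR) procedure, a list of the same kind came from pooled reads of both replicates, and a thresholded list held the peaks the authors kept as the optimal IDR set. The peak caller, aligner, versions and IDR threshold are not given in the sources used here. The signal value of each peak was used as a score that the authors' caller wrote, relative to a control and on a scale that is not stated, and it served only to rank or describe peaks within a list. The −log10 q-value of each peak was deposited by the authors in the column that the narrowPeak form keeps for it, and it had the same upper limit for many peaks (2831 of 15658 in the pooled ce11 list), so peaks were not ranked by it. Its values ran from 0.677 to 2.32 in the pooled list, and all 57 thresholded peaks had the highest one. Peaks of the relaxed lists therefore include background: the lowest signal value of the pooled list was 2.00 and the median 2.95, against 16.4 to 56.9 in the thresholded list, whose peaks were the 57 of highest signal value in the pooled list.

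Peaks had a fixed width of 470 bp in replicate 1, of 416 bp in replicate 2 apart from 3 narrower peaks, and of 370 bp in the pooled list apart from 7 narrower peaks of 92 to 155 bp. With these widths, distances shorter than a peak are poorly resolved. The depth per sample is unknown, so no interval for a peak's own value could be given. Intervals of shares are exact Clopper-Pearson intervals at 95% and cover counting error only. With 2 replicates of 1 group, p-values compare peaks with random positions or genes with other genes, and say nothing about variation between animals.

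Gene starts, biotypes and exons came from Ensembl release 115 (WBcel235, the coordinates of ce11), with 19985 protein-coding genes, and sequence from the RefSeq assembly of the same build. No ce11 peak passed a chromosome end. Mitochondrial genes without a name took that of the RefSeq gene with the same start. Annotated starts of many genes in this animal are trans-splice sites and may lie downstream of the true start of transcription. Summits came from the lists. The feature of a summit was called in the order coding exon, UTR, noncoding RNA gene, intron, intergenic, and piRNA genes were not counted.

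The comparisons were fixed before the data were examined. Overlap of the replicates used the 1000 peaks of highest signal value in each list, an overlap of at least 1 bp, and 1000 circular shifts along each chromosome (one-sided, smallest p 0.001). Distance to gene starts used a window of 500 bp and 1000 sets of random positions on the same chromosomes, the mitochondrial genome included (two-sided, smallest p 0.002). Gene lists were tested with a two-sided Fisher's exact test over a window from 1000 bp upstream to 500 bp downstream, against all other genes of the same class, with Benjamini-Hochberg adjustment over 13 lists and separately over 5 small RNA biotypes. The class of the small RNA list was taken as noncoding genes without piRNA genes and pseudogenes, a choice made after the annotation was read. The lists were homeobox, nuclear receptor, ribosomal protein, proteasome, histone, cuticle collagen, markers of epidermis, muscle, pharynx, intestine, germline and neuron, and small structured RNA genes. The names elt-5 and opt-2 had no match in the annotation, and 50 histone names stand for 72 genes because names repeat. The ceh-82 and unc-119 loci were tested with 1000 random windows. For 5 words an exact McNemar test compared sequence within 50 bp of summits with windows 250 bp to either side. The count of thresholded peaks on each build had no test.

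Genes named in the text followed a rule set before the data were examined: the protein-coding gene with the nearest start for the 25 strongest thresholded peaks, up to 4 members of each list with a thresholded peak in the window, ceh-82 and unc-119, and the 5 strongest pooled peaks outside the thresholded list. Other genes named, such as those in counts of 5 or fewer, were chosen after their values were seen. Correlations used 100000 permutations. The sequence TCGCGCAGGGAG, for sites of the dosage compensation complex, was written from general knowledge and is not a published position matrix. Tests of the X share, the X and autosomal difference and the nearest collagen genes were added after the positions were seen.

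Alternatives changed the window, the number of peaks, the overlap rule, the random model, the build, the set of gene starts and the threshold, and left out each replicate by using the other replicate's own strongest peaks. Others left out mitochondrial or X peaks, and were chosen after seeing the data. The tests were first run on simulated peaks. With 150 of 1000 peaks planted in both lists the overlap test found 159, and it called 1 of 20 unplanted sets. With 24 of 57 peaks planted at gene starts 30 were found near one (permutation p = 0.002) and 0 of 20 unplanted sets were called. Both of the 2 planted lists of the 13 were called with 0 others, and 1 of 20 unplanted sets gave a call. With TAATTA written into 15 of 57 windows 15 were found, and 0 of 20 unplanted sets were called. These simulated peaks lay at random nuclear positions, so they do not cover the higher GC content at the real summits. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.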

Results

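The data describe which chromatin was recovered by immunoprecipitation of the tagged homeobox protein CEH-82 (gene F45C12.2) in the nematode Caenorhabditis elegans. Whole larvae of the fourth larval stage, both sexes pooled, carried a transgene for the protein fused at its C-terminal end to GFP and a FLAG tag. Chromatin was sheared by sonication, immunoprecipitated and sequenced (ChIP-seq). The 2 samples were biological replicates of 1 group, so the comparisons were between the replicates, between peaks and random positions, and between groups of genes. The control used by the authors when peaks were called was not analysed here, so no peak or gene group below is shown to be bound by the protein. The deposited ce11 lists held 4561 peaks for replicate 1, 8651 for replicate 2 and 15658 for the pooled reads of both, all called at a relaxed threshold. The authors' thresholded list held 57 peaks, which are called reproducible below only because they are the authors' IDR set. Of the 57, 48 overlapped a peak of both replicates, and of its 7 mitochondrial peaks 1 overlapped a peak of replicate 2. Read depth is unknown from these lists. All coordinates are on ce11, and a negative distance lies upstream of a gene start.

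The strongest reproducible signal lay on the X chromosome, away from the starts of protein-coding genes. The peak of highest signal value, 56.9, covered X:13700807-13700941 in an intergenic stretch 6026 bp from the start of K02D3.1. Next came an intergenic peak at X:8036259-8036628, signal value 49.3 and 4869 bp upstream of xol-1, the X-linked switch gene of sex determination. That peak was closer to noncoding genes, with its summit at -230 bp from the start of C18A11.13 and 313 bp downstream of the start of the tRNA gene WBGene00022939. The peak ranked 3 lay at X:6296487-6296625 in an intron of mom-1, signal value 48.9, with the start of cest-16 as the nearest at 3390 bp. The strongest autosomal peak, III:3867508-3867662 with signal value 47.6, lay 280 bp upstream of rpl-3, which encodes a protein of the large ribosomal subunit. The mitochondrial peak M:12295-12664, signal value 47.4, fell in the coding exon of ND5, a subunit of the respiratory chain's NADH dehydrogenase.

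Further down the 25 strongest peaks, the intergenic peak at X:11094139-11094230 (signal value 44.3) lay 3998 bp downstream of the start of W02H3.3. An autosomal peak at III:10759198-10759307 (40.5) lay 54 bp upstream of tasp-1, and a peak at IV:654708-655077 (40.0) lay 317 bp upstream of rpl-15. On X followed peaks nearest to nspc-17 (39.9), ZK899.6 (38.7), C41A3.2 (38.6, in a coding exon of the polyketide synthase gene pks-1), F20B6.9 (37.8) and F22H10.2 (35.9). The peak at II:10563380-10563749, signal value 31.9, lay 158 bp upstream of cdc-48.1, which encodes an AAA ATPase of protein quality control. X peaks nearest to F19H6.5, gtr-1, fbxb-58 and F55G7.5 had signal values of 30.6, 29.3, 29.0 and 28.3. A mitochondrial peak of 27.7 fell in the coding exon of ND4, 408 bp upstream of WBGene00010964. It was followed by peaks nearest to eelo-2 on IV (26.6, 236 bp upstream), Y41G9A.17 on X (26.6, intronic) and T27A8.7 on X (26.4). The last of the 25 lay at rpl-35 on III (26, 465 bp upstream), in the mitochondrial COX2 gene (23.3) and near T24D8.6 on X (23). The next peaks by signal below the reproducible set lay 276 bp upstream of wwp-1 (16.3), in a coding exon of F58G1.7 beside the small nuclear RNA gene sup-6 (16.1), 28 bp upstream of the trehalase gene tre-1 (16.1), in the 5' UTR of the homeobox gene ceh-38 (15.9) and 1273 bp upstream of T28C6.7 (15.5).

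**Figure D1:**
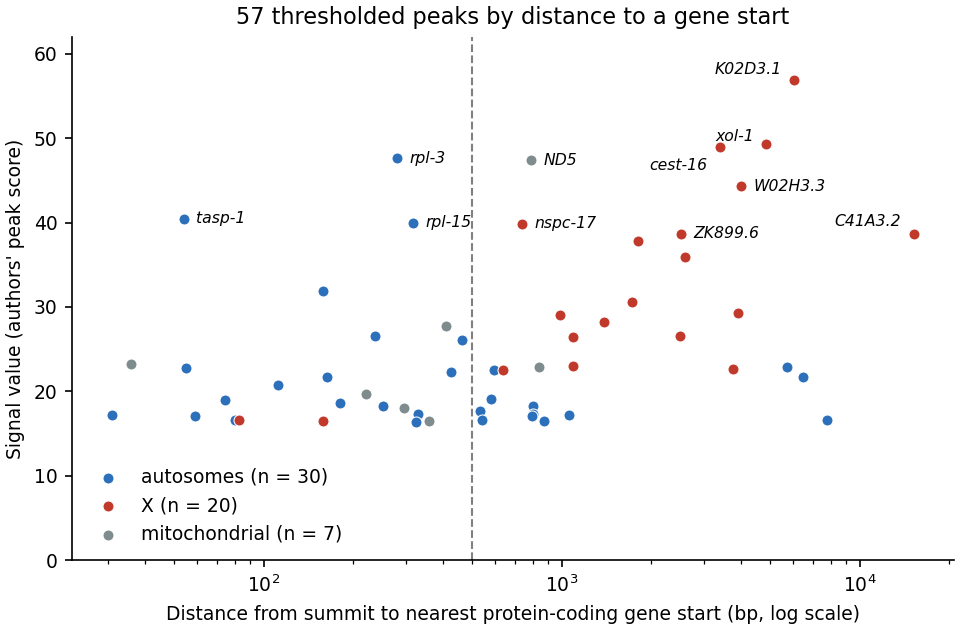
Signal value of the 57 reproducible peaks (vertical axis, the authors' peak score) against the distance from the summit to the nearest protein-coding gene start (horizontal axis, bp, log scale); each point is 1 peak and the dashed line marks 500 bp. Of the 20 X peaks, 15 lie beyond 1000 bp, against 4 of the 30 autosomal peaks.

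By chromosome, 20 of the 57 reproducible peaks were on X, 30 on the autosomes and 7 on the mitochondrial genome. Chromosome V, the longest, carried 1, inside pxn-1 at the snoRNA gene ZK994.7 (signal value 22.9). The other autosomes carried 7 (I), 7 (II), 8 (III) and 7 (IV). X took 40% of the 50 nuclear peaks (exact 95% interval 26.4 to 54.8%), while it makes up 17.7% of the nuclear genome (exact binomial p = 0.000233, two-sided). In the whole pooled list X took 17% of 15640 nuclear peaks (16.4 to 17.6%). Among the 25 strongest peaks X took 16 of 22 nuclear peaks in the pooled list, 9 of 11 in replicate 1 and 16 of 24 in replicate 2. The sequence TCGCGCAGGGAG, with at most 2 mismatches, lay within 100 bp of 13 of the 20 X summits and of 0 of the 30 autosomal summits, where the exact 95% upper limit was 11.6%. The strongest X peak, nearest to K02D3.1, held it only with 5 mismatches, and 7 of 149 other X peaks among the 1000 strongest pooled peaks held it with at most 2. The X share and this sequence were looked at after the positions had been seen, and the intervals cover counting error only.

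**Figure D2:**
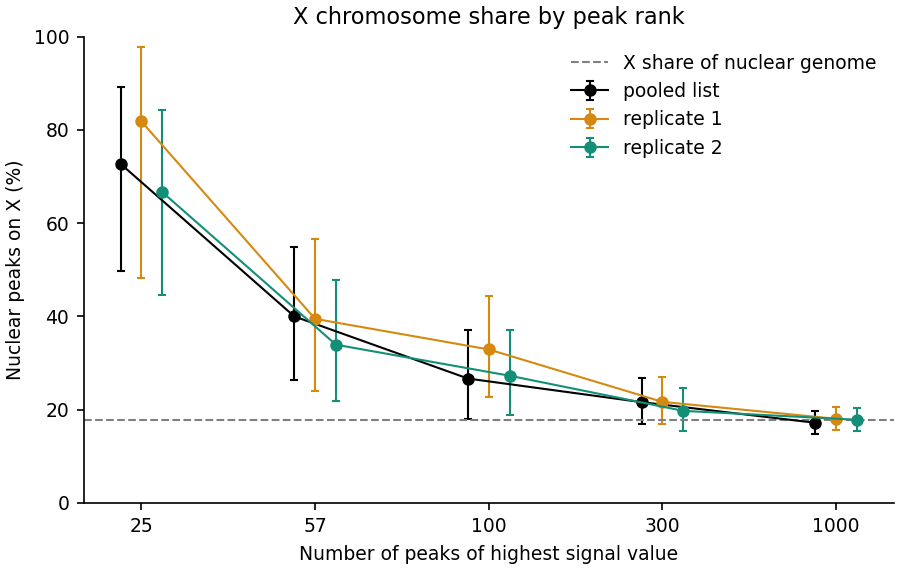
Share of nuclear peaks on the X chromosome (vertical axis, %) among the strongest 25, 57, 100, 300 and 1000 peaks (horizontal axis) of the pooled list and of each replicate; bars are exact 95% intervals and the dashed line is the X share of the nuclear genome, 17.7%. The pooled share is 72.7% at 25 peaks and 17.2% at 1000.

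The replicates were compared by how many of their strongest peaks overlapped. Of the 1000 peaks of replicate 1 with the highest signal value, 159 overlapped one of the 1000 strongest peaks of replicate 2 by at least 1 bp, which was 15.9% (exact 95% interval 13.7 to 18.3%). Circular shifts of replicate 2's peaks gave 1.01% on average and at most 2.3%, a 15.7-fold difference (one-sided permutation p = 0.001, the smallest that 1000 draws can give). Among the reproducible peaks, 54 overlapped a peak of replicate 1, 51 a peak of replicate 2 and 48 a peak of both. All 20 X peaks were in both lists, as were 27 of the 30 autosomal peaks, but these lists include background. Among replicate 1's 1000 strongest peaks were matches for 22 of the 30 autosomal and all 20 X peaks. Its 57 strongest matched 11 and 12. All 30 autosomal peaks matched one of replicate 2's 1000 strongest. The peaks at rpl-15 and ZK994.7 had replicate 1 signal values of 2.80 and 2.75, near that list's median of 2.66. The autosomal peaks near eif-3.C, iff-2 and trap-3 overlapped no peak of replicate 1. Of the 7 mitochondrial peaks, 1 overlapped a peak of replicate 2, the one in ND5. The mitochondrial genome held 24 peaks in replicate 1, covering 64.7% of its length, and 2 in replicate 2, covering 6.03%. Across the 48 peaks found in both, the signal values of the replicates had a Pearson r of 0.384 (permutation p = 0.0082, adjusted 0.0246 over 3 sets of peaks) and a Spearman rho of 0.368 (permutation p = 0.0112, adjusted 0.0336). Within the 20 X peaks r was 0.308 (permutation p = 0.186, adjusted 0.279) and rho 0.289 (p = 0.217, adjusted 0.325). Within the 27 autosomal peaks r was 0.200 (permutation p = 0.320, adjusted 0.320) and rho -0.0302 (p = 0.886, adjusted 0.886). Neither set passed the test, which with so few peaks does not show that the relation was absent there. Replicate 2's signal value was higher at 47 of the 48 peaks, but the scale of each list is not given in the sources used here, so this shows no difference in binding. The correlations are across peaks, which are not independent replicates.

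Autosomal peaks lay close to the starts of protein-coding genes and X peaks did not. On the autosomes 18 of 30 summits (60%) were within 500 bp of a start, among them those at rpl-12 (31 bp upstream), tasp-1 (54 bp), epc-1 (59 bp), the translation factor gene iff-2 (80 bp) and egl-30, the Gq alpha subunit gene. On X 2 of 20 summits (10%) were that close, those at C28G1.2 and T13C5.6. The median distance was 326.5 bp on the autosomes and 2155.5 bp on X. Of the 25 strongest peaks 16 were on X, and 0 of these 16 lay within 500 bp. Over all 57 peaks the share was 43.9% (25 peaks, exact 95% interval 30.7 to 57.6%), against 24.1% for random positions on the same chromosomes (two-sided permutation p = 0.002, the smallest possible). Autosomal peaks alone gave 60% against 18.5% (permutation p = 0.002) and X peaks alone 10% against 15.1% (permutation p = 0.765). The shares on X and autosomes differed by Fisher's exact test (p = 0.000422), a split chosen after the values were seen. With the strongest peaks of replicate 1 alone, many of them mitochondrial, the share was 40.4% against 35.5% (permutation p = 0.432), and among the 29 peaks with the higher signal values it was 31% (permutation p = 0.418).

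Summits were mostly outside annotated genes. Of the 57, 37 were intergenic, 7 in coding exons, 6 in noncoding RNA genes, 5 in introns of protein-coding genes, 2 in 5' UTRs and 0 in 3' UTRs. The coding exon summits included 5 on the mitochondrial genome, in ND5, ND4, COX2 and ND1, and those in pks-1 and mdt-26. The 5' UTR summits were in ints-4, which encodes an Integrator subunit, and C28G1.2. An intronic summit in ints-8, another Integrator gene, lay at -20 bp from the start of rpr-1, the RNA component of RNase P. A pair of partly overlapping peaks, I:4171999-4172368 and I:4172199-4172568, lay beside the spliced leader RNA gene sls-2.4.

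Ribosomal protein genes and small structured RNA genes had more peaks at their starts than other genes. From 1000 bp upstream to 500 bp downstream of the start, 5 of 78 ribosomal protein genes held a reproducible summit: rpl-3, rpl-15, rpl-35, rpl-20 (signal value 21.7) and rpl-12 (17.2). Other protein-coding genes held one in 44 of 19907 cases (odds ratio 30.9, Fisher's exact test, adjusted p = 8.62e-06). In the list of tRNA, snRNA, snoRNA, rRNA and miRNA genes, 27 of 1392 held one, against 13 of 8058 other noncoding genes (odds ratio 12, exact test, adjusted p = 6.21e-13). These 27 included 17 tRNA genes, 7 snoRNA genes, the spliced leader genes sls-2.4 (22.5) and sls-2.1 (19.1), 1 mitochondrial rRNA gene and 0 miRNA genes. By biotype, tRNA (exact test, adjusted p = 9.47e-10) and snoRNA genes (adjusted p = 0.00136) passed the test, and snRNA, rRNA (both adjusted p = 0.129) and miRNA genes (0.629) did not. The snRNA call was gained with the 300 strongest pooled peaks (8 genes, exact test, adjusted p = 0.00387), with replicate 2's peaks alone (3 genes, 0.0211) and with piRNA genes and pseudogenes in the background (0.0288). The rRNA call was gained with replicate 1's peaks alone (2 genes, exact test, adjusted p = 0.0115) and with that background (0.0422). Without mitochondrial peaks and genes 3 tRNA genes were left, WBGene00022939, WBGene00022947 and WBGene00023221 (exact test, adjusted p = 0.365), while 12 genes of the whole small RNA list held a summit (odds ratio 5.48, adjusted p = 0.000448). With replicate 2's strongest peaks alone, 16 genes of the whole list held one (odds ratio 6.23, exact test, adjusted p = 9.81e-06), 3 of them tRNA genes (adjusted p = 0.769). The snoRNA call was lost with a window from 500 bp upstream (2 genes, exact test, adjusted p = 0.393) and with replicate 1's peaks alone (2 genes, adjusted p = 0.845). Nested or neighbouring genes share a peak: the summit at rpl-15 also counted for the snoRNA genes K11H12.12 and K11H12.13, and these genes cannot be separated at this resolution. The mitochondrial peak in COX2 (signal value 23.3) counted for the tRNA genes KEF34_t17 to KEF34_t21 and the rRNA gene KEF34_r01. Fisher's test treats genes that share a peak as independent, so its p-values for the small RNA genes overstate the evidence.

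No other list passed the test at the reproducible peaks. Cuticle collagens had 1 of 172 genes, col-93 (signal value 18.3; exact test, adjusted p = 1). Homeobox genes had 0 of 99 (exact 95% upper limit 3.66%), nuclear receptors 0 of 269 (1.36%), histones 0 of 72 (4.99%) and proteasome subunits 0 of 33 (10.6%). The tissue lists also had 0 genes each: epidermis of 20, muscle of 36, pharynx of 18, intestine of 27, germline of 41 and neuron of 30. With 49 of 19985 protein-coding genes holding a summit, 0 was the most probable count for lists of this size.

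The 1000 strongest pooled peaks gave the same 2 lists. Of the 78 ribosomal protein genes 29 held a summit (37.2%, exact 95% interval 26.5 to 48.9%), against 2.67% of other genes (odds ratio 21.6, Fisher's exact test, adjusted p = 1.86e-24). Beyond the 5 above, the strongest were rps-12 (signal value 15.2), rps-28 (14.7), rpl-38 (11.4) and rps-1 (11.1). Of the small structured RNA genes 187 held one (13.4% against 3.25%, exact test, adjusted p = 5.03e-45), made up of 80 tRNA, 73 snoRNA, 15 snRNA, 17 miRNA and 2 rRNA genes. Among these biotypes tRNA (exact test, adjusted p = 4.66e-16), snoRNA (6.79e-28) and snRNA genes (0.00192) passed, and miRNA (0.227) and rRNA genes (0.281) did not. The miRNA call was gained with a window from 2 kb upstream (26 genes, exact test, adjusted p = 0.0119), by nearest start (36 genes, 0.00472), with replicate 2's peaks alone (23 genes, 0.00188) and with piRNA genes and pseudogenes in the background (1.69e-05). Without mitochondrial peaks and genes 58 of 612 tRNA genes held a summit (9.48% against 4.16%, exact test, adjusted p = 1.21e-07). Counts depended on the replicate: with replicate 1's peaks alone 15 ribosomal protein genes (19.2%), 101 small RNA genes and 24 snoRNA genes held a summit, and with replicate 2's alone 43 tRNA genes did. Each of these calls passed the test all the same. Homeobox genes had 1 of 99, ceh-38 (exact test, adjusted p = 0.821), and nuclear receptors 3 of 269, nhr-142, nhr-255 and nhr-1 (adjusted p = 0.246). Histone genes had 5 of 72, his-37, his-35, his-41, his-67 and his-68 (exact test, adjusted p = 0.210), proteasome genes 3 of 33, rpn-3, rpn-9 and rpn-11 (adjusted p = 0.210), and collagens 8 of 172 (adjusted p = 0.338). Muscle had 2 of 36, unc-112 and unc-60 (exact test, adjusted p = 0.498), neuron 1 of 30, snb-1 (0.821), and epidermis, pharynx, intestine and germline 0 each. When each peak was given to its nearest gene start, 37 of the 172 collagen genes were named (exact test, adjusted p = 1.75e-15), and the tRNA call was lost (62 genes, adjusted p = 0.225). With replicate 2's strongest peaks alone, histones (6 genes, exact test, adjusted p = 0.0431) and collagens (11, 0.0316) passed, and with replicate 1's alone collagens did (11, adjusted p = 0.00479). Near-identical copies, as among histone and tRNA genes, cannot be told apart by reads that match more than 1 of them.

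**Figure D3:**
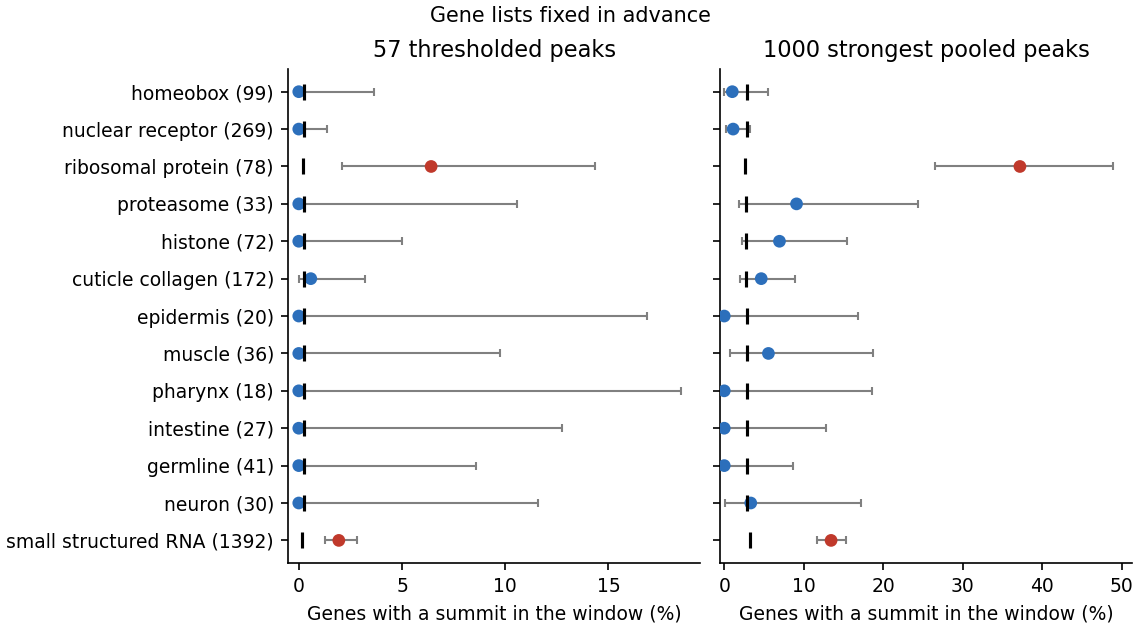
Share of the genes of each list (horizontal axis, %) with a peak summit from 1000 bp upstream to 500 bp downstream of the start, at the 57 reproducible peaks and at the 1000 strongest pooled peaks; list sizes are in parentheses. Points are shares with exact 95% intervals, red where the adjusted p was under 0.05, and black ticks are the shares of all other genes of the class. Ribosomal protein genes reach 6.41% and 37.2%.

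The ceh-82 and unc-119 loci were examined because a transgene can carry extra copies of such sequence, which can give signal. Signal values were relative to a control that was not analysed here, so the counts cannot show whether extra copies were present. The labels name the transgene as an extrachromosomal array and also speak of an insertion, so its form and copy number were not settled. At ceh-82 (WBGene00018433, II:1732232-1733291) 4 pooled peaks lay within 20 kb, against 6.46 in random windows of the same length (one-sided permutation p = 0.78). The strongest of the 4 had a signal value of 3.15 and rank 6769, and 0 lay inside the gene. The nearest reproducible peak was 411.62 kb from the start of ceh-82. At unc-119 (WBGene00006843, III:10902641-10908935), the gene mutated in the strain, 6 pooled peaks lay within 20 kb against 6.99 in random windows (permutation p = 0.607). One of them lay inside the gene, with a signal value of 8.78 and rank 350 in the pooled list. Neither window held a reproducible peak. In replicate 1's list alone both counts were above random, 3 against 1.84 at ceh-82 (permutation p = 0.285) and 3 against 2.1 at unc-119 (permutation p = 0.339). The central 95% of random windows held 1 to 15 pooled peaks for ceh-82 and 1 to 16 for unc-119. For replicate 1's list these ranges were 0 to 6 and 0 to 7.

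Homeodomain proteins often bind sequences with a TAAT core. TAATTA occurred within 50 bp of 4 of the 57 reproducible summits (7.02%) and in the flanking windows of 2 (3.51%; exact McNemar test, adjusted p = 0.908 over 5 words). With replicate 1's strongest peaks alone the difference was -1.79 percentage points (exact test, adjusted p = 1), so TAATTA had no stable direction. The shorter TAAT was less frequent at summits than in flanks, in 28 against 44 peaks (49.1% against 77.2%, exact test, adjusted p = 0.0186). GC content was higher at summits than in the same flanks, by a median of 16.3 percentage points on autosomes and 11.9 on X. The word tests do not adjust for this, so a lower share of a word made only of A and T says nothing particular about the homeodomain core. GAGAGA was more frequent, in 9 peaks against 1 (15.8% against 1.75%, exact test, adjusted p = 0.0195). CACGTG was found in 1 peak and in 1 flank (exact test, adjusted p = 1), and TGATAA in 5 and 3 (adjusted p = 0.908). Against random positions within 2 kb in place of the flanks, neither TAAT (exact test, adjusted p = 1) nor GAGAGA (adjusted p = 0.547) passed at the 57 peaks, and with 100 bp windows TAAT did not (adjusted p = 0.0879). With replicate 2's strongest peaks alone neither passed (exact test, adjusted p = 0.313 for both), and with replicate 1's alone GAGAGA did not (adjusted p = 0.938). In the 999 of the 1000 strongest pooled peaks with complete windows, TAAT was at 43.2% of summits against 58.2% of flanks (exact McNemar test, adjusted p = 6.20e-11) and GAGAGA at 18.7% against 7.31% (adjusted p = 3.07e-14). TGATAA was lower there, 6.01% against 8.71% (exact test, adjusted p = 0.0451), and neither TAATTA (2.90% against 3.90%, adjusted p = 0.260) nor CACGTG (3.1% against 1.90%, adjusted p = 0.130) passed. Against random positions within 2 kb TAATTA passed there, lower at summits (2.92% against 4.83%, exact test, adjusted p = 0.0430).

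The authors deposited the lists on 2 genome builds. Both reproducible lists held 57 peaks, with 20 on X in each. Chromosome I held 7 peaks on ce11 and 6 on ce10, and the mitochondrial genome 7 and 8. No coordinates were converted between builds.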

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

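The alternatives that left out X or mitochondrial peaks, kept X peaks alone, kept piRNA genes and pseudogenes in the background, used the 57 strongest peaks of each replicate, or searched for words in autosomal or the 1000 pooled peaks were chosen after the data were seen; the others were planned. Replicate overlap stayed above random in all 9 alternatives (8.9 to 40.4%), and it cannot be computed without either replicate. Across the main comparisons 43 alternatives kept direction and side of the threshold, 2 were stronger, 2 weaker and 9 reversed; for single lists 260 kept both, 15 were stronger, 5 weaker and 26 reversed. The cause was not tested for any of the changes below. With the 29 strongest peaks the share near gene starts was 31%, with X peaks only it was 10%, below random, and without replicate 1 or 2 it ranged from 35.1 to 40.4%. Replicate 1's 57 strongest peaks, behind the 40.4%, include 19 mitochondrial ones and had a random share of 35.5%. TAATTA, 3.51 percentage points above the flanks at the 57 peaks, had no stable direction: it ranged from -1.79 to 1.75 points without a replicate, was -3.33 at autosomal peaks and -1.0 at the 1000 pooled peaks, and -1.91 there against random positions (exact test, adjusted p = 0.0430; 0.0430 to 1 over the alternatives), while the other differences missed the threshold. Peaks near ceh-82 numbered 0 to 3 without a replicate, the 3 of replicate 1 being above the random mean of 1.84. Near unc-119 there were 22 within 50 kb against 17 at random, 1 among the 1000 strongest pooled peaks against 0.409, and 3 without either replicate, above random in replicate 1; none of these passed the test. Ribosomal protein and small structured RNA genes passed at thresholded peaks in all 10 alternatives. At the 1000 pooled peaks 4 lists passed with 2 kb upstream (nuclear receptors, 3 genes and below other genes, and collagens were added), and 3 to 4 without one replicate. The lists that changed direction had few genes and missed the threshold after the change. At thresholded peaks collagens had 0 genes with 500 bp upstream and 0 with the 29 strongest peaks, snRNA 0 with the 29 strongest, rRNA 0 without mitochondrial peaks and 0 without X and mitochondrial peaks, and tRNA 1 without X and mitochondrial peaks; homeobox ranged from 0 to 1 and rRNA from 0 to 2 without a replicate. With 300 pooled peaks proteasome had 2, histones 3, neuron 1 and miRNA 5. At the 1000 pooled peaks epidermis and neuron had 1 each with 2 kb upstream, and by nearest start histones had 2, epidermis 1, germline 3 and rRNA 1; rRNA had 0 without mitochondrial peaks. Without a replicate, histones ranged there from 1 to 6, epidermis from 1 to 2, intestine from 0 to 1, neuron from 0 to 1, rRNA from 0 to 2 and miRNA from 6 to 23; the 6 histone and 23 miRNA genes, and the 2 rRNA genes at replicate 1's strongest 57 peaks, passed. Unknown read depth limits what missing peaks show. No paired analysis was possible because there was only 1 group.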

Other observations

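The tests of the nearest gene for each list, of X peaks among all pooled peaks, of the coverage of the mitochondrial genome and of distances at small RNA genes, and the score interval for TAATTA, which replaced a bootstrap, were chosen after the results they bear on were seen; those of sequence under the peaks were set out before they were run, although the patterns were already known.

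Cuticle collagen genes, which encode the structural proteins of the worm's cuticle, often had the protein-coding gene start nearest to a strong peak. Most of these summits lay outside the start window, with 8 of 40 inside it. Of the 1000 strongest pooled peaks 40 lay nearest to 37 of the 172 collagen genes, against 6.17 genes when the peaks were shifted along the chromosomes (5.99-fold, one-sided permutation p = 0.001, the smallest possible, adjusted 0.006 over 12 lists). Of these 40 summits 29 lay more than 500 bp downstream of the start, 15 inside the gene and 18 past its end, and 14 lay within 300 bp of the gene's end. Examples were col-138 (1197 bp downstream, signal value 12.4), sqt-3 (1985 bp, 10.8), bli-2 (1107 bp, 10.5) and dpy-13 (909 bp, 7.88). For ribosomal protein genes 21 of 30 such summits lay inside the start window, and the 2 lists were not compared by a test. Proteasome genes were also above shifts, with 4 genes against 0.773 (permutation p = 0.006, adjusted 0.024). Fisher's exact test against other genes by nearest start did not pass for these 4 of 33 genes (adjusted p = 0.139).

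Of 58 nuclear tRNA genes with a summit of the 1000 strongest pooled peaks from 1000 bp upstream to 500 bp downstream of the start, 29 had it within 100 bp upstream of the start. For snoRNA genes 17 of 73 had it there, for snRNA genes 4 of 15 and for miRNA genes 1 of 17. These counts were not compared by a test.

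The X peaks away from protein-coding gene starts might mark sites that recruit the dosage compensation complex, the machinery that lowers X expression in hermaphrodites of this animal. The 12-base word TCGCGCAGGGAG, a form of the motif known at such sites that was written from general knowledge rather than taken from a published matrix, was present with at most 2 mismatches within 100 bp of 65% of X summits (13 of 20, exact 95% interval 40.8 to 84.6%) and of 0 of 30 autosomal summits (Fisher's exact p = 2.18e-07). At 100 random sets of 20 X positions the mean was 0.06 peaks and the highest 1, and permuted words gave 0.17 on average. The strongest X peak, however, had 5 mismatches. Of 149 other X peaks among the 1000 strongest pooled peaks 7 (4.7%) held the word, a lower share than the 65% above. Random sets of that size were not drawn. An excess of DNA or reads from the whole chromosome is argued against by the X share of 17% among all pooled nuclear peaks, and repeated sequence by a median of 0% of an X peak's 31-base words found more than once. Whether the tagged protein is at these sites or they give signal in any such experiment stays open, since no biological explanation was tested against another group of samples and the authors' control was not analysed here.

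The mitochondrial peaks of replicate 1 could come from a general excess of mitochondrial DNA in that sample. Replicate 1's peaks covered 64.7% of the mitochondrial genome and those of replicate 2 covered 6.03%, while no nuclear chromosome was covered beyond 2.41% in replicate 1. They took 19 of replicate 1's 57 strongest peaks and 1 of replicate 2's. The tRNA call at the 57 reproducible peaks was lost without mitochondrial peaks and genes (3 genes left), while that at the 1000 strongest pooled peaks was not (58 nuclear genes). No biological explanation was tested, and a difference in how the control was used for the samples stays open.

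Base composition and a homeodomain core were looked at as explanations of the autosomal peaks, many of them at gene starts. The values here cover all 30 autosomal peaks, of which 18 lay within 500 bp of a gene start. TAATTA was at 0 of the 30 summits (exact 95% upper limit 11.6%), which argues against that exact word lying under most of these peaks. It was in 1 flank, a difference of -3.33 percentage points (95% score interval -16.7 to 8.34). The shorter TAAT was at 10 of the 30 summits and in 23 flanks (exact McNemar test, adjusted p = 0.0221). Neither difference is adjusted for GC content, so they cannot show whether a homeodomain core matters at these peaks. GC content within 50 bp of the summit was above the flanks by a median of 16.3 percentage points (51.5% against 35.6%), in 26 of 30 peaks (exact sign test p = 5.95e-05). X peaks showed a median difference of 11.9 points, higher in 20 of 20, so GC content does not separate them from autosomal peaks. GC content was compared only with flanks of the same peaks, not with gene starts that lack a peak. Whether GC-rich sequence draws the protein, or shears and amplifies better, stays open, and no biological explanation other than those words was tested.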
